A study of Arabidopsis thaliana with 24 samples.

How the data were processed

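Gene expression was measured in shoots of Arabidopsis thaliana with 24 one-colour Affymetrix arrays, 4 for each of 6 groups. The groups combined 3 genotypes with 2 root treatments of 24 h. Col-0 is the wild type, ipt3,5,7 carries mutations in 3 genes of cytokinin biosynthesis, and abcg14 is affected in a transporter that moves cytokinin from root to shoot. In the treatment called C.KNO3 both sides of a divided root system stood in 1 mM KNO3, and in the treatment called Split one side stood in 1 mM KNO3 and the other in 1 mM KCl. Per the labels' protocols, plants grew in short days (8 h light, 16 h dark, 23 °C and 21 °C) with 0.5 mM ammonium succinate, 0.1 mM KNO3 and 3 mM sucrose. Roots were divided around day 14, plants then spent 4 days without nitrate, and they reached the divided plates around day 18. Per the series' design text, 4 independent experiments were made and 3 plants were pooled in each sample. RNA was extracted with Trizol, and biotin-labelled material was made from 100 ng of total RNA with the GeneChip WT PLUS kit, per the labels' protocols.

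The values used were those the authors deposited, 1 per probe set and array for 38408 probe sets, and no scanner file was used here. Affymetrix Expression Console and GCRMA are named in the submitters' processing notes, without versions, and GCRMA corrects background by probe sequence, normalizes between arrays and summarises probes. The deposited values were taken as log2 from their range of 0.08 to 12.93, since no source used here states the base of the logarithm. With another base every difference on the log scale would change by one common factor, the folds would change by different amounts, and the tests would not change. Array medians over all probe sets lay between 3.46 and 3.66. Background was not estimated here, and folds with a level below these medians hold for the deposited values alone. Build, filters and settings of the upstream steps are not given in the sources used here. The precision of every value is limited by the number of arrays, 4 per group.

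Probe sets were named through a table that pairs them with the platform annotation, and symbols were updated through gene identifiers in a RefSeq table of the assembly TAIR10.1, which served only for names and for the order of neighbouring genes. Of the 38408 probe sets, 16746 were paired with 1 gene, 758 with several genes, and 20904 had no gene named here. Probe sets with several genes were not used to name a gene. Where a gene had more than 1 probe set (163 genes), the one with the highest mean over all arrays was kept, which left 16554 genes. Of these, 16418 were found in the RefSeq table and 136 were not, 1804 carried a symbol and 14750 a locus code. The naming was uneven. A named probe set existed for 17.5% of the protein-coding genes that have a symbol (1840 of 10492) and for 89.7% of those known by a locus code (15314 of 17070). As a result the mutated genes IPT3, IPT5, IPT7 and ABCG14 had no named probe set and were not analysed here, so the genotype labels were not checked on the mutated genes themselves.

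Comparisons between groups were made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), with 1 mean per group fitted to all 24 arrays. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the 16554 genes within each of 11 comparisons, and a gene was called at an adjusted p under 0.05. All adjusted p-values given for single genes came from limma. The genes named are, for each comparison, the 10 called genes with the largest rise and the 10 with the largest fall (5 and 5 between the mutants and for differences of response), up to 4 members with the smallest adjusted p of each gene list, and, where no gene was called, the 5 genes with the smallest p. Genes named outside this rule were chosen after their values had been seen, and this holds for the genes shared by all mutant comparisons, for the members of the chromosome 3 segment and for NAI2. Lists of genes were fixed by locus code, 23 in all. The 6 lists with at least 3 named members were tested with camera (preset correlation of 0.01 between genes), beside camera with an estimated correlation and fry, all in limma, and adjusted over the lists within a comparison. The others were given as values per gene. Because few fixed lists had enough members, 64 families of at least 5 genes were also formed from the letters of gene symbols, after the files had been examined and before any family was tested.

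The replicate number of the labels was read as marking the shared experiment, since the design text states 4 independent experiments and each group holds numbers 1 to 4. The labels do not say so in as many words. Over the 60 pairs of arrays with the same number in different groups, deviations from the group means correlated with a mean r of 0.21 across genes (from -0.19 to 0.47, 51 pairs over 0.1), against -0.07 over 180 pairs with different numbers (from -0.49 to 0.49). Deviations cancel within a group, so the second mean is tied to the first and is no separate baseline. The fit without the experiment is given first, a choice made after the counts of both fits had been seen, and the fit with the experiment as a block stands beside it where a count or a call differs. Each experiment holds 1 array per group, so no test within an experiment was possible.

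The response to Split was also read in data not used to choose the genes. In each of 4 rounds 100 genes were chosen in Col-0 without 1 experiment. They were the rising and the falling genes with the smallest p, in equal numbers. Their mean signed difference was read in the experiment left out, with an exact sign-flip permutation test over the 4 values. The overlap of the mutants was set beside 100 simulations of unchanged groups against the same Col-0 arrays, beside the number expected from independent lists, and beside the overlap with the Col-0 arrays divided between the mutants in 6 ways. The steps were tested on simulated data, with noise drawn independently for each gene and array and no effect of the experiment. With 200 changed genes among 16554, simulated as Split minus C.KNO3 in Col-0 with 4 against 4 arrays in 10 runs, the fit recovered 22.4% of genes changed by 0.5 on the log2 scale, 87.3% of those changed by 1 and 99.5% of those changed by 2, with 4.8% false calls.

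Alternatives were a further quantile normalization, centring of each array on its median, removal of the 33.3% of genes with the lowest mean level (11036 left), the experiment as a block, a fit on the groups of the comparison alone, a robust variance prior, the mean of all probe sets of a gene, all probe sets each on its own, and every experiment and every array left out in turn. The table carried no mark for control probe sets, so none were removed from the fit on all probe sets. Experiments 1 and 2 alone, experiments 3 and 4 alone, and the removal of the chromosome 3 segment were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.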

Results

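Shoots of Arabidopsis were profiled on 24 arrays after 24 h of nitrate supply to both sides of a divided root system (C.KNO3) or to one side (Split), in wild-type Col-0 and in the cytokinin mutants ipt3,5,7 and abcg14. Each of the 6 groups held 4 arrays, 1 from each of 4 independent experiments, and 16554 genes were tested. Within a group, arrays correlated with r of at least 0.971 across the tested genes and of at least 0.959 across all probe sets. The design asks which shoot genes respond to nitrate on one side of the roots, and whether that response needs cytokinin made by IPT3, IPT5 and IPT7 or transported by ABCG14.

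In Col-0 the shoot genes with the smallest p for Split minus C.KNO3 differed by less than 2-fold. AT4G39955 read 5.57 ± 0.14 on Split against 4.99 ± 0.17 on C.KNO3 (log2, SD, n = 4), a difference of 0.57 (SE 0.13). AT3G24080 differed by 0.60 (SE 0.14), AT1G09370 by -0.54 (SE 0.14), AT1G16860 by -0.49 (SE 0.12) and AT5G51520 by -0.57 (SE 0.15). None of these passed, with limma adjusted p = 0.999 for each. Genes of the nitrate response that could be read were not called either, with or without the experiment as a block. Their standard errors here are those without the block and so hold the spread between experiments. AT1G25550, AT1G68670 and AT3G25790, which encode repressors of the GARP family that respond to nitrate, differed by 0.45 (SE 0.56), 0.24 (SE 0.31) and -0.07 (SE 0.21). AT5G41670, a 6-phosphogluconate dehydrogenase, differed by 0.25 (SE 0.18), and NRT2.5, a high-affinity nitrate transporter, by 0.13 (SE 0.17). ARR15, a type-A response regulator that cytokinin induces within minutes, differed by -0.01 (SE 0.46), with arrays at 2.96 to 4.16 on Split and 1.66 to 4.90 on C.KNO3. Over all genes limma called 0 genes in this comparison, with 572 genes at an unadjusted p under 0.05 where chance gives 828, and with the experiment as a block it called 0, with 803. The median standard error of a difference was 0.1666, and in simulation the fit recovered 22.4% of genes changed by 0.5 and 87.3% of those changed by 1 with 4 against 4 arrays. The simulated noise was independent between genes and arrays, while real arrays of an experiment share deviations. These shares may therefore not hold for the real comparison.

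In ipt3,5,7 the genes with the smallest p for Split were AT5G56610 (0.48, SE 0.13), AT2G43800 (-0.62, SE 0.17), AT4G00590 (-0.57, SE 0.16), AT2G04680 (0.74, SE 0.21) and AT4G22410 (0.72, SE 0.20). In abcg14 they were AT4G36590 (-0.38, SE 0.10), AT4G11550 (-0.70, SE 0.18), the MADS-box gene AGL101 (-0.78, SE 0.21), AT1G62000 (-0.69, SE 0.19) and AT1G36510 (0.47, SE 0.13). For the mean of the 3 genotypes they were AT5G56840 (0.48, SE 0.11), AT1G36510 (0.31, SE 0.08), AGL104 (-0.32, SE 0.08), AT1G09370 (-0.30, SE 0.08) and AT3G21945 (-0.45, SE 0.12). No gene in these comparisons passed, and every adjusted p in limma was 1 at 3 digits. The counts were 0 genes in ipt3,5,7 (304 at an unadjusted p under 0.05), 0 in abcg14 (407) and 0 for the mean (377), and the fit with the experiment as a block also called 0, with 392, 551 and 573. Fold changes of Split in different genotypes correlated across genes with r of -0.03, -0.01 and 0.03, where genes are not independent replicates.

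The test of whether the response to Split differed between a mutant and Col-0 called 0 genes for ipt3,5,7 and 0 for abcg14 with limma, with 471 and 459 at an unadjusted p under 0.05, and 0 and 0 with the block, with 644 and 618. The genes with the smallest p for ipt3,5,7 minus Col-0 were AT4G00234 (-0.51, SE 0.13), AT4G06688 (1.01, SE 0.26), AT5G33393 (0.73, SE 0.19), AT1G10100 (0.80, SE 0.21) and AT5G41780 (0.97, SE 0.26). For abcg14 minus Col-0 they were AT1G24250 (-0.96, SE 0.24), AT2G27320 (0.83, SE 0.22), AT1G43310 (0.82, SE 0.23), AT1G78720 (0.84, SE 0.24) and AT3G57580 (-0.67, SE 0.19). When 100 genes were chosen for their Split response in Col-0 without 1 experiment, their mean signed difference was 0.588 ± 0.024 in the experiments used to choose them. In the experiment left out it was 0.035 ± 0.059 in Col-0 (SD, n = 4, above 0 in 3 of 4, exact permutation p = 0.25). It was 0.002 ± 0.070 in ipt3,5,7 and -0.002 ± 0.128 in abcg14, with an exact permutation p of 1 for each. With 4 values no exact p can reach 0.05. The held-out value in ipt3,5,7 minus Col-0 was -0.033 ± 0.046 (exact permutation p = 0.25) and that in abcg14 minus Col-0 was -0.037 ± 0.115 (exact permutation p = 0.625).

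**Figure D1:**
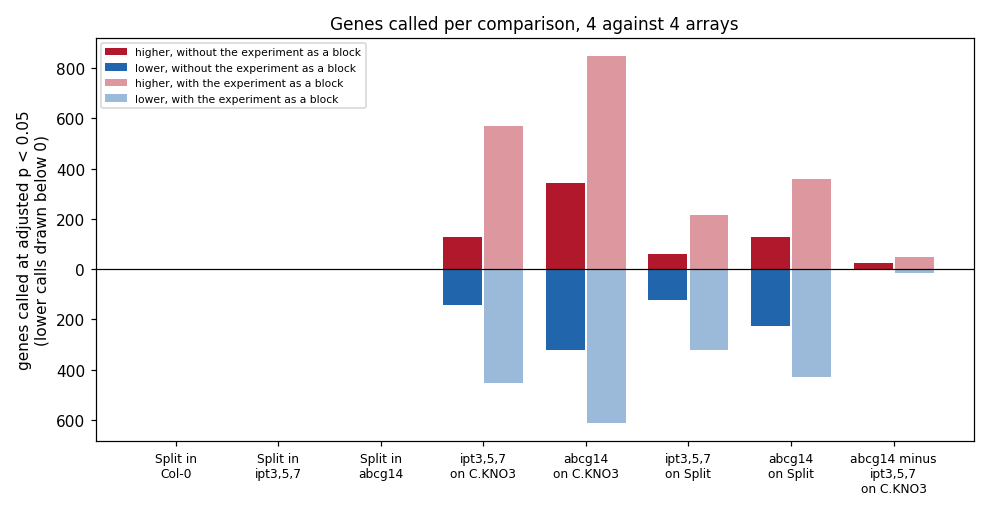
Bars give the number of genes called at an adjusted p under 0.05 in each comparison of 4 against 4 arrays, with higher calls above 0 and lower calls below, without and with the experiment as a block. The 3 Split comparisons call 0 genes, and the mutants call 180 to 665 genes without the block and 540 to 1459 with it.

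With nitrate on both sides, the genes with the largest changes in ipt3,5,7 shoots against Col-0 shoots were mostly known by a locus code alone. CCS, the copper chaperone of superoxide dismutase, rose from 4.84 ± 0.25 to 6.87 ± 0.49 (log2, SD, n = 4), a 4.07-fold rise (SE 0.31 on the log2 scale, adjusted p = 0.000882). ARPN, a blue copper protein called plantacyanin, rose by 1.69 (SE 0.41, adjusted p = 0.0361), and MED9, a Mediator subunit, by 1.49 (SE 0.28, adjusted p = 0.00628). AT1G66100 fell most, from 6.80 ± 1.43 to 2.97 ± 0.50, a 14.2-fold fall (adjusted p = 7e-04). TRY, a MYB repressor of trichome formation, changed by -2.18 (SE 0.45), ASPGB1, an asparaginase, by -2.13 (SE 0.27), the beta-expansin EXPB3 by -2.21 (SE 0.46) and the cellulase GH9C2 by -2.01 (SE 0.50). ATMRK1, a Raf-related protein kinase, had the smallest p of all genes and read 3.52 ± 0.24 against 5.89 ± 0.15 in Col-0 (adjusted p = 5.59e-11). Further rises were AT1G24530 (2.14), AT5G14940 (1.74), AT2G04050 (1.74), AT3G44970 (1.63), AT5G41020 (1.52), AT2G29370 (1.45) and AT1G57590 (1.44). Further falls were AT3G16670 (-2.95), AT3G46490 (-2.70), AT5G22580 (-2.46) and AT3G10185 (-1.94). In all, 269 genes were called, 127 higher and 142 lower, and 103 of them changed more than 2-fold. With the experiment as a block 1026 were called (571 higher, 455 lower), which included all 269. After a further quantile normalization the split was 95 higher and 170 lower.

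The count of 269 depended on single arrays. It was 80 without Col-0 replicate 2, 119 without Col-0 replicate 1, 85 without ipt3,5,7 replicate 4, 92 without ipt3,5,7 replicate 3 and 442 without ipt3,5,7 replicate 2, and 161 when only the arrays of the comparison entered the fit. Of the 21 called genes named for this comparison, CCS, AT5G14940, ATMRK1, ASPGB1, AT1G66100 and AT3G46490 stayed called in all of the 7 alternative settings run for single genes, and 15 lost the call in at least 1, mostly with a whole experiment left out.

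In abcg14 on C.KNO3 the gene with the largest rise was OSM34. This osmotin-like defence protein rose from 3.72 ± 0.62 to 6.47 ± 1.46 (log2, SD, n = 4), a 6.72-fold rise (adjusted p = 0.0233). GID1A, a gibberellin receptor, rose from 4.68 ± 0.29 to 6.57 ± 0.35, a 3.71-fold rise (adjusted p = 2.38e-06), and lies in a segment of chromosome 3 described further on. ARPN rose by 2.23 (SE 0.41, adjusted p = 0.00239) and MT1B, a metallothionein, by 1.77 (SE 0.39, adjusted p = 0.00954). AT3G16670 fell from 6.56 ± 0.62 to 2.27 ± 0.84, a 19.5-fold fall, and AT5G42530 from 9.19 ± 0.22 to 6.02 ± 0.52, a 9.04-fold fall (adjusted p = 0.000162 and 1.97e-06). The abcg14 arrays read AT3G16670 at 1.42 to 3.23, below the array medians over tested genes of 3.29 to 3.46 and in a range where background, which was not estimated here, can limit a fold. TRY changed by -2.67 (SE 0.45) and GH9C2 by -2.40 (SE 0.50). Further rises were AT5G44572 (2.10), AT1G72900 (2.10), AT1G35350 (1.94), AT4G01870 (1.86), AT2G30930 (1.78) and AT4G37180 (1.77). Further falls were AT1G66100 (-3.57), AT3G46490 (-3.04), AT5G01015 (-2.68), AT5G22580 (-2.47), AT1G67750 (-2.39) and AT2G27402 (-2.28). The cold-induced gene KIN1 was also higher, at 1.98 ± 0.29 against 1.37 ± 0.28 (adjusted p = 0.0361, and 0.0904 to 0.146 with 1 experiment left out). A total of 665 genes were called, 342 higher and 323 lower, 220 of them by more than 2-fold. The block raised this to 1459 (847 higher, 612 lower), with all 665 included, and quantile normalization gave 272 higher and 399 lower.

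Left-out arrays lowered the abcg14 count on C.KNO3 of 665 to 253 (abcg14 replicate 4), 305 (abcg14 replicate 3), 285 (Col-0 replicate 2) and 310 (Col-0 replicate 1). Of the 22 called genes named there, 11 stayed called in all 7 settings, among them GID1A, TRY, AT3G16670, AT5G42530 and AT1G66100, and 11 lost the call in at least 1, among them OSM34, KIN1 and MT1B.

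With nitrate on one side of the roots, ipt3,5,7 again had higher CCS (6.91 ± 0.31 against 5.38 ± 0.29, log2, SD, n = 4, adjusted p = 0.0128) and ARPN (5.29 ± 0.26 against 3.58 ± 0.39, adjusted p = 0.0388). Lower genes were AT1G66100 (-3.51, SE 0.55), MSRB6, a methionine sulfoxide reductase (-2.14, SE 0.29), ATMRK1 (-2.09, SE 0.14), ASPGB1 (-2.06, SE 0.27) and TRY (-2.02, SE 0.45). ARR15 was lower by 2.01 on that scale, at 1.48 ± 0.35 against 3.49 ± 0.52 (adjusted p = 0.0303). Further rises were AT1G57590 (1.52), AT3G44970 (1.39), AT1G34060 (1.39), AT2G29370 (1.38), AT1G62370 (1.32), AT5G14940 (1.18), AT4G37180 (1.17) and AT5G47330 (1.06). Further falls were AT3G16670 (-3.06), AT3G46490 (-2.92), AT5G22580 (-2.37) and AT1G24147 (-1.98). In total 180 genes were called, 59 higher and 121 lower, 70 of them by more than 2-fold, and 540 (217 higher, 323 lower) with the block, which kept all 180. The count was 61 and 65 without ipt3,5,7 replicates 3 and 4, and 89, 81 and 105 without Col-0 replicates 1, 2 and 4. ASPGB1, AT1G66100, AT3G46490, ATMRK1 and MSRB6 stayed called in all 7 settings, and the other 15 of the 20 named genes did not.

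On the same treatment abcg14 showed rises of OSM34 (2.66, SE 0.68), ARPN (2.39, SE 0.41), GID1A (1.84, SE 0.20) and ICL, the isocitrate lyase of the glyoxylate cycle (1.69, SE 0.42, adjusted p = 0.0294). AT1G66100 fell by 3.63 on the log2 scale (SE 0.55), ASPGB1 by 2.52 (SE 0.27) and MSRB6 by 2.48 (SE 0.29). TRY changed by -2.17 (SE 0.45), and UGT76C2, a cytokinin N-glucosyltransferase, was at 2.70 ± 0.41 against 4.15 ± 0.45 in Col-0 (SD, n = 4, adjusted p = 0.0245). Further rises were AT5G64120 (2.07), AT3G15650 (1.81), AT4G01870 (1.68), AT3G28540 (1.63), AT1G62370 (1.60) and AT2G29370 (1.59). Further falls were AT3G16670 (-3.46), AT3G46490 (-3.36), AT5G42530 (-2.84), AT5G01015 (-2.55), AT5G22580 (-2.40) and AT1G67750 (-2.37). There were 354 calls, 129 higher and 225 lower, 154 of them beyond 2-fold. The block gave 786 (358 higher, 428 lower), with all 354 kept, and the fit on the arrays of the comparison alone gave 234. The count was 147 without abcg14 replicate 4, 200 without Col-0 replicate 1 and 214 without Col-0 replicate 2. Of 22 named genes, 11 stayed called in all 7 settings, and UGT76C2, OSM34 and ICL were among those that did not.

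A set of 79 genes passed in all 4 comparisons of a mutant with Col-0, 60 lower and 19 higher, and those named here were picked after their values had been seen. Both mutants were compared with the same Col-0 arrays on each treatment. The set was not formed again with an experiment left out, where ipt3,5,7 on Split called 27 to 86 genes in all. The 7 settings for single genes were not run on the genes named here in these comparisons. Lower genes included the peroxidase PRXCA (-1.92 in ipt3,5,7 and -2.15 in abcg14 on C.KNO3), the cellulase GH9B8 (-1.74 and -1.92), the thionin THI2.2 (-1.65 and -1.73) and SNZ, an AP2-type repressor of flowering (-1.30 and -1.58). The thylakoid ascorbate peroxidase TAPX (-0.76 and -1.09) and ACLB-1, a subunit of ATP citrate lyase (-0.46 and -0.43), were lower as well. Higher genes included the vacuolar processing enzyme GAMMA-VPE (1.05 and 0.87), the glucosinolate transporter GTR2 (0.87 and 1.08), the alanine aminotransferase AlaAT1 (0.69 and 0.90), the sphingolipid enzyme DPL1 (0.95 and 0.85) and SDH1-1 of succinate dehydrogenase (0.40 and 0.49). AT4G39955 was higher by 1.34 and 1.44 on C.KNO3 and by 0.96 and 0.89 on Split. Of the ipt3,5,7 calls, 117 were shared by both treatments in the same direction, and of the abcg14 calls 264 were. The differences between treatments in mutant effect are those of the interaction tests, which called 0 genes.

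ARR15 was lower than in Col-0 in every mutant group, by -1.81 and -2.09 on C.KNO3 and by -2.01 and -2.12 on Split in ipt3,5,7 and abcg14, respectively (adjusted p = 0.0456, 0.0108, 0.0303 and 0.0131). On C.KNO3 it was lower in 3 of the 4 experiments, since Col-0 replicate 1 read 1.66 where the other Col-0 arrays read 3.25 to 4.90. The mutant arrays of both treatments read ARR15 at 0.79 to 2.66, below the array medians over tested genes of 3.29 to 3.46. Background, which was not estimated here, can limit the size of a difference in that range. The ipt3,5,7 call on C.KNO3 was lost after quantile normalization (adjusted p = 0.0603) and without experiment 2, 3 or 4 (adjusted p = 0.289, 0.352 and 0.129). The abcg14 call on C.KNO3 was lost without the same experiments (adjusted p = 0.143, 0.0949 and 0.0689), the ipt3,5,7 call on Split also (adjusted p = 0.232, 0.0983 and 0.202), and the abcg14 call on Split without experiment 2 or 4 (adjusted p = 0.132 and 0.184). RR16, another type-A regulator, differed in abcg14 on C.KNO3 by -0.52 (SE 0.19, adjusted p = 0.13) and did not pass. UGT76C2 passed in abcg14 on Split but not without experiment 2 or 4 (adjusted p = 0.198 and 0.257), and its response to Split differed from that of Col-0 by -0.70 (SE 0.49, adjusted p = 1). UGT76C1, which acts on the same substrates, differed by -0.21 in abcg14 on Split (SE 0.15), and the type-B regulator RR18 by -0.16 (SE 0.15), and neither passed.

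**Figure D2:**
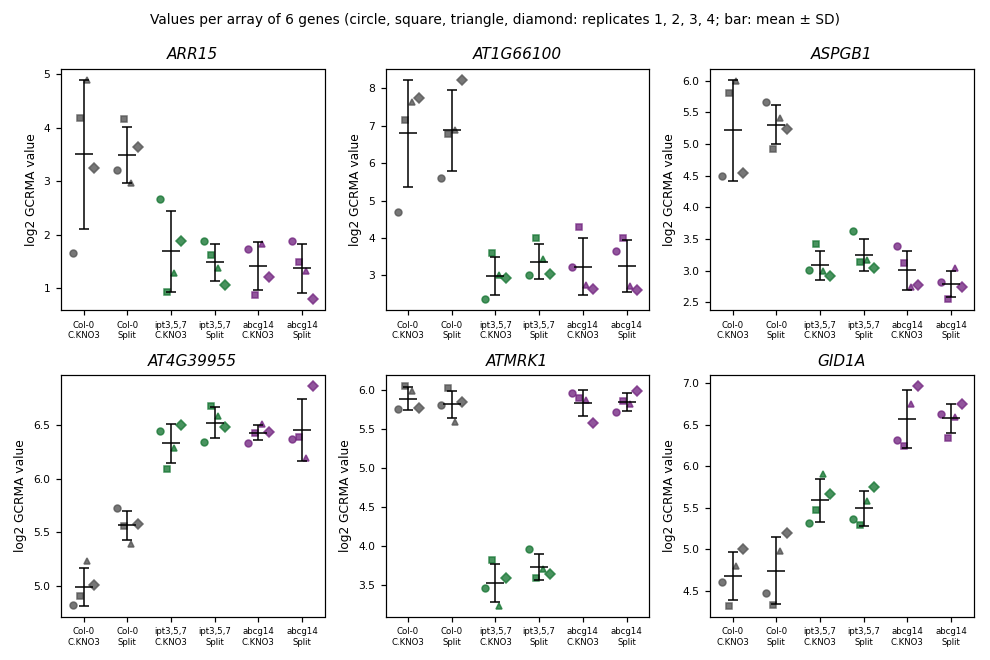
Points give the log2 GCRMA value of each of the 24 arrays for 6 genes, with the group mean and SD as bars (n = 4) and a symbol per replicate number. ARR15, AT1G66100 and ASPGB1 read lower and AT4G39955 higher in both mutants, and ATMRK1 reads 3.52 and 3.72 in ipt3,5,7 against 5.82 and 5.84 in abcg14. GID1A reads lowest in Col-0, higher in ipt3,5,7 and highest in abcg14, at 6.57 and 6.58 in the last.

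Calls of both mutants on C.KNO3 overlapped in 186 genes, 85 higher in both and 101 lower in both, where independent lists would share 2.6 and 2.8, and 0 genes were called in opposite directions. TRY, GH9C2, ASPGB1 and ARPN are among the shared genes. The fold changes correlated across genes with r = 0.81, against 0.50 in 100 simulations of unchanged groups set against the same Col-0 arrays, and the covariance was 0.085 against 0.019, a difference of 0.067. With the Col-0 arrays divided 2 and 2 between the mutants, in 6 ways, r was 0.55 on average, the covariance 0.068, and 12 to 33 genes were shared from the smaller lists that 2 controls gave. On Split 118 genes were shared (28 higher against 0.5 expected, 90 lower against 1.6, 0 opposite), with r = 0.78 and a covariance of 0.066 against 0.50 and 0.019 in simulation. Divided controls gave r = 0.48, a covariance of 0.049 and 8 to 19 shared genes there. With the block the overlap was 716 genes on C.KNO3 and 369 on Split, with 0 in opposite directions.

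The mutants were compared with each other on C.KNO3. ATMRK1 was 4.94-fold higher in abcg14 than in ipt3,5,7 (5.82 ± 0.17 against 3.52 ± 0.24, log2, SD, n = 4, adjusted p = 1.02e-10). The transcription factor gene bZIP58 was higher by 1.32 (SE 0.28), RTFL7, a small peptide of the ROTUNDIFOLIA family, by 1.08 (SE 0.18), SEC, an O-GlcNAc transferase, by 1.00 (SE 0.10) and AT3G04920 by 0.99 (SE 0.17). AT5G42530 was lower at 6.02 ± 0.52 against 8.27 ± 0.52, AT1G67860 differed by -1.18, AT1G33640 by -1.07, AT5G58390 by -0.91 and AT1G53800 by -0.54. Of these 10 genes, ATMRK1, SEC, AT5G42530 and AT1G67860 stayed called in all 7 settings and 6 did not. bZIP58 lost the call after quantile normalization (adjusted p = 0.0619) and without each of the 4 experiments (adjusted p = 0.0561 to 0.552), AT5G58390 (adjusted p = 0.0905 to 0.291) and AT1G53800 (adjusted p = 0.0746 to 0.221) without each experiment, AT1G33640 without 3, and RTFL7 and AT3G04920 without 2. In all 29 genes were called, 24 higher and 5 lower, 6 of them by more than 2-fold, and 62 (47 higher, 15 lower) with the block. The fit on these arrays alone called 6, and 8 were called (4 higher, 4 lower) with the segment below left out. PYK10, a beta-glucosidase abundant in roots, differed by 1.32 (SE 0.34, adjusted p = 0.232, and 0.039 with the block). The mutants were not compared on Split.

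Of the 24 genes higher in abcg14 than in ipt3,5,7, 19 lay in a single stretch of chromosome 3 between AT3G03980 and AT3G05165, which holds SEC, AT3G04920 and GID1A. The stretch was found after the values had been seen. Its ends were set with the same differences between abcg14 and Col-0. High values inside and low values beside it therefore follow in part from that choice, and the array pairs below are the same arrays. Among its 82 named genes, the 44 with a mean level above the median gene had a median difference of 0.77 between abcg14 and Col-0 (quartiles 0.65 and 0.94, log2), a 1.70-fold difference, and 43 of the 44 were above 0. The other 38, at low levels, had a median of -0.01. The 60 genes flanking it had a median of -0.01, and the same 44 genes in ipt3,5,7 a median of 0.05. In abcg14, 36 genes of the stretch were called higher on C.KNO3 and 30 on Split, with 0 called lower on C.KNO3. In ipt3,5,7 on C.KNO3 1 was called, GID1A. It was higher there than in Col-0 in each experiment, at 5.31 to 5.91 against 4.32 to 5.00, so its rise was not particular to abcg14. The median was 0.68 to 0.95 in each of the 8 pairs of abcg14 and Col-0 arrays from the same experiment and treatment. Relative to all other genes of such levels the median was 0.72 as deposited, 0.71 after quantile normalization and 0.72 after centring. A window of 15 genes reached a median of 0.85 there, and 0 of 1000 shuffled orders of the 8188 genes held one as high (highest 0.60). ABCG14 itself lies on chromosome 1.

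**Figure D3:**
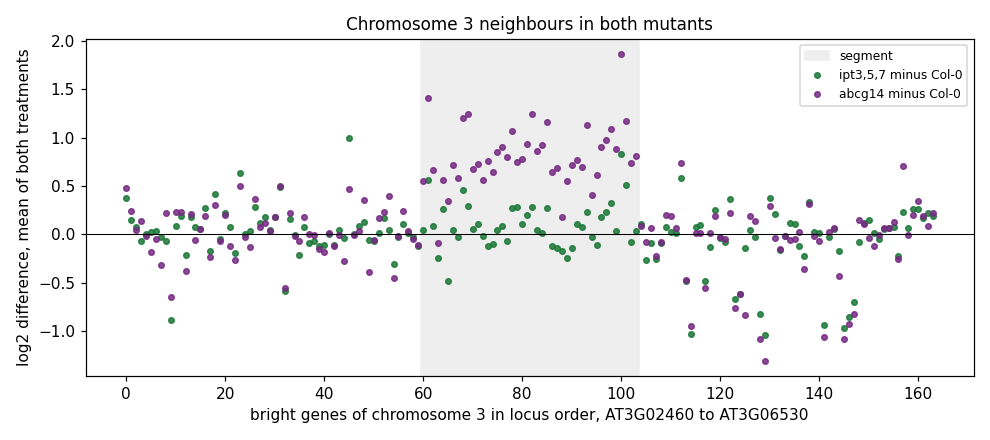
Points give the log2 difference from Col-0 (mean of both treatments) of genes above the median level along chromosome 3, from AT3G02460 to AT3G06530, for ipt3,5,7 and abcg14. In the shaded stretch the abcg14 points have a median of 0.77 and the ipt3,5,7 points one of 0.05.

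Of the 23 gene lists fixed in advance, 6 could be tested, in 66 tests over the 11 comparisons, and 2 tests passed with the preset correlation. Light-harvesting proteins were lower in ipt3,5,7 than in Col-0 on Split, with LHCB4.2 at -0.50 (SE 0.15), LHCB4.1 at -0.23, LHB1B2 at -0.19 and LHCB4.3 at -0.27 (median -0.25, 0 of 4 members above 0, camera adjusted p = 0.00852). With an estimated correlation the adjusted p was 0.112, without experiment 1 it was 0.0758 and without another experiment 0.00784 to 0.027, fry gave 0.0271, and no member was called over all genes against 1 lower when adjusted over the list alone. Replicate 3 of ipt3,5,7 on Split was the lowest array of its group in LHCB4.2 (6.62), LHCB4.1 (7.36) and LHB1B2 (9.61). The list did not pass in the other mutant comparisons, though its medians there were similar. They were -0.17 in ipt3,5,7 on C.KNO3, and -0.23 and -0.19 in abcg14 on C.KNO3 and Split (camera adjusted p = 0.261, 0.312 and 0.329). In abcg14 on Split 2 members were lower adjusted over the list alone. The abscisic acid and cold list was lower on Split than on C.KNO3 in abcg14, with KIN1 at -0.47 (SE 0.17), COR15A at -0.72 (SE 0.56), LTI30 at -0.34 and COR47 at -0.31 (median -0.34, 0 of 5 above 0, camera adjusted p = 0.0317). With an estimated correlation its adjusted p was 0.465, with fry 0.718 and without the dimmest genes 0.338, and adjusted over the list alone 1 member was lower. Without experiments 2, 3 or 4 its call was lost (adjusted p = 0.0774, 0.135 and 0.0558), and without experiment 1 it stayed (adjusted p = 0.0203). On C.KNO3 1 member of that list, KIN1, was called higher in abcg14, against 2 adjusted over the list alone, the other being LTI30 at 1.14 (SE 0.40, adjusted p = 0.11, and 0.0323 with the block). Both are near the low end of the scale, and the brighter members differed both ways, with KIN2 at 6.21 ± 0.53 against 6.87 ± 0.32, COR15A at 8.47 ± 0.78 against 8.97 ± 0.55 and COR47 at 7.97 ± 0.50 against 7.62 ± 0.61 (log2, SD, n = 4). The list as a whole did not pass there (camera adjusted p = 0.312, and 0.543 with an estimated correlation). With the block COR15A was called lower in ipt3,5,7 on both treatments and in abcg14 on Split (adjusted p = 0.0422, 0.0468 and 0.0331).

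Of the other 4 testable lists, no member was called without the block in any comparison. With the block, AT4G14090 of the flavonoid list was called higher in abcg14 on C.KNO3 (0.72, adjusted p = 0.0446), in ipt3,5,7 on Split (1.06, adjusted p = 0.00718) and, with UF3GT (1.05, adjusted p = 0.032), in abcg14 on Split (1.31, adjusted p = 0.000612). PYE of the iron list was called lower with the block in ipt3,5,7 and abcg14 on C.KNO3 (-0.89 and -0.78, adjusted p = 0.0204 and 0.0321), and AT1G47395 in ipt3,5,7 (-1.88, adjusted p = 0.0469). The CC-type glutaredoxins, a family that responds to nitrate and cytokinin, had 20 measured members with a median of 0.00 for Split in Col-0, and adjusted over the list alone 1 was lower in abcg14 on C.KNO3, AT2G30540 at -0.87 (SE 0.25, adjusted p = 0.0513, and 0.0313 with the block). The nitrate response list had 4 measured members, of which 1, AT5G41670 at 0.62 in abcg14 on C.KNO3 (SE 0.18, adjusted p = 0.0564, and 0.0395 with the block), was higher adjusted over the list alone. Of the flavonoid and anthocyanin list, DFR, UF3GT and AT4G14090 had a median of 1.05 in abcg14 and 0.96 in ipt3,5,7 on Split against Col-0 (camera adjusted p = 0.105 and 0.128, and 0.000528 and 0.00264 with the block). The block also brought this list past the threshold for Split against C.KNO3 in ipt3,5,7 (median 0.75, adjusted p = 0.00155), in abcg14 (0.35, adjusted p = 0.015) and for the mean (0.36, adjusted p = 0.00257). Of the iron list, PYE, BHLH101 and the peptide genes AT1G47400 and AT1G47395 had a median of -1.03 in ipt3,5,7 on C.KNO3 (camera adjusted p = 0.073, and 0.00726 with the block). There, without the block, the camera adjusted p was 0.0534, 0.00691, 0.3 and 0.164 with experiment 1, 2, 3 or 4 left out. With the block the iron list also passed in ipt3,5,7 on Split (median -0.68, adjusted p = 0.0288) and for Split in Col-0 (-0.56, adjusted p = 0.0367) and the mean (-0.29, adjusted p = 0.0368). The light-harvesting list for Split in ipt3,5,7 (median -0.19, adjusted p = 0.0325), the abscisic acid and cold list for the mean of Split (-0.14, adjusted p = 0.0368) and for the difference of response in abcg14 (-0.57, adjusted p = 0.0138) passed with the block alone. The block was not combined with an estimated correlation. Without the block, that correlation gave these tests adjusted p-values of 0.345 to 0.903.

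For 10 lists 1 or 2 members could be read. Besides the type-A regulators, cytokinin metabolism and transport, and cytokinin receptors and type-B regulators described above, these were nitrate transport (NRT2.5 at 0.49 in ipt3,5,7 on Split, SE 0.17, adjusted p = 0.199), sulfur deficiency (BGLU28 at -0.24 in ipt3,5,7 on C.KNO3, SE 0.22), aliphatic glucosinolate synthesis (AT2G31790 at -0.31, SE 0.25) and the jasmonate response (PDF1.2 at 0.05, SE 0.12), none of which passed. GI, read as a check of harvest time, differed by 0.15 in ipt3,5,7 and -0.21 in abcg14 on C.KNO3 (SE 0.26). PYK10, read as a check for root tissue, was at 9.40 ± 0.30 in Col-0 and 8.33 ± 0.87 in ipt3,5,7 on C.KNO3 (SD, n = 4, adjusted p = 0.11, and 0.026 with the block). NAI2, a protein of the endoplasmic reticulum bodies that hold PYK10, was lower in ipt3,5,7 on C.KNO3 by -0.94 (adjusted p = 0.00828), and higher in abcg14 than in ipt3,5,7 by 0.98 (adjusted p = 0.0109). The jacalin-related lectins JAL22, JAL23, JAL31, JAL33 and JAL34 had a median of -0.92 in ipt3,5,7 on C.KNO3, 0 of 5 above 0 (camera adjusted p = 0.00842, and 0.611 with an estimated correlation). Their median was -0.43 in ipt3,5,7 on Split (adjusted p = 0.14, and 0.92 with an estimated correlation) and -0.06 in abcg14 on C.KNO3 (adjusted p = 0.497, and 0.827 with an estimated correlation). Unequal amounts of root tissue were not excluded by these genes. CLV3, a meristem marker, lay between 0.98 and 1.14 in all group means. The isopentenyltransferases, cytokinin response factors, ammonium assimilation, phosphate starvation, cell cycle, salicylate and defence, and senescence lists had 0 members with a named probe set and were not analysed here.

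Experiments and genotypes both separated the arrays. The first principal component held 28.7% of the variance, and its mean score was -14.5, -11.6, 9.4 and 16.6 in experiments 1 to 4. By group it was -25.5 ± 11.9 and -16.1 ± 11.3 in Col-0 on C.KNO3 and Split, 7.4 ± 18.6 and 8.6 ± 17.2 in ipt3,5,7, and 12.4 ± 20.4 and 13.2 ± 15.9 in abcg14 (SD, n = 4). Each experiment held all 6 groups. Of the genes called on C.KNO3 in experiments 1 and 2 alone, 139 of 152 in ipt3,5,7 and 373 of 394 in abcg14 had the same sign in experiments 3 and 4. Of those called in experiments 3 and 4 alone, 127 of 128 and 262 of 277 had the same sign in experiments 1 and 2.

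**Figure D4:**
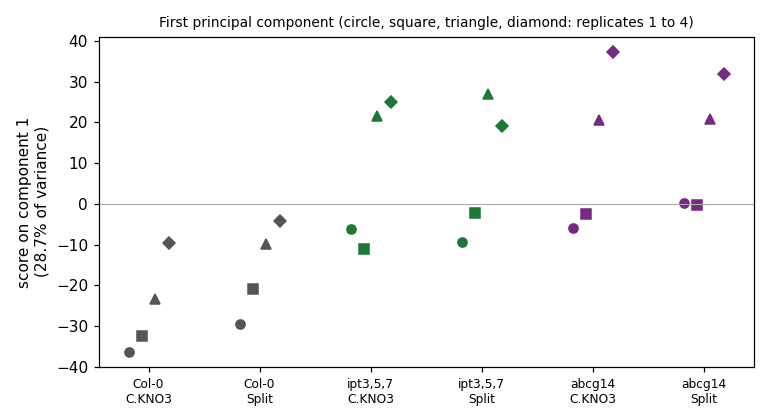
Points give each array's score on the first principal component (28.7% of the variance) by group, with a symbol per replicate number. The Col-0 groups have the lowest means, -25.5 and -16.1, and within each group experiments 3 and 4 score higher than experiments 1 and 2.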

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

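The splits of the arrays were set before their results were seen, and the tests of chance clustering, probe-binding variants, an extra copy, parts of the experiments, plant or RNA state, and both windows around the mutated loci were chosen after. Other splits of the same arrays into groups of 4 were fitted alike. Of 35 splits, only the real one called as many genes in ipt3,5,7 on C.KNO3 (269, highest other 2), abcg14 on C.KNO3 (665, highest other 1), ipt3,5,7 on Split (180, highest other 0) and abcg14 on Split (354, highest other 0). That is 1 of 35 each, the smallest share these splits can give, and they ignore the pairing of arrays by experiment. Among the 8 splits that part all 4 pairs of arrays from an experiment, the real one alone was as large, with at most 1 gene in another. The smallest share there is 1 of 8, which cannot fall under 0.05. The other splits mix the genotypes, so any difference between genotypes widens the spread in them and lowers their counts. The size of the gap therefore does not measure chance, only the rank does, and chance was not excluded.

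For Split the real count was 0, which every split reaches, so 35 of 35 did in Col-0 (highest other 5), in ipt3,5,7 (221) and in abcg14 (135), 100 of 100 for the mean of the genotypes (1496), and 100 of 100 for the differences of response in ipt3,5,7 (1) and abcg14 (39). The splits with 221 and 135 genes set experiments 1 and 2 against 3 and 4, and the draw with 1496 set mostly experiments 3 and 4 against 1 and 2, which points to a structure of the samples by experiment. Between the mutants 29 genes were called by the real split, 1 of 35, and 28 by the split of experiments 1 and 2 against 3 and 4. With the experiment as a block the count was 62.

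Single arrays stood apart from the other 3 of their group in 21 of 480 tests, which covered 79 genes and the array median in each of 6 groups, where chance flags about 1 in 20 groups, or 24. The gap divided by the range, past the 95% limit of the Dixon test, was 0.984 for AT1G53800, 0.915 for AT5G51520, 0.884 for MT1B, 0.881 for AT3G16670, 0.865 for CCS and 0.855 for AT3G21945 in ipt3,5,7 on C.KNO3. In ipt3,5,7 on Split it was 0.901 for AT3G04920, 0.869 for AT3G24080, 0.868 for AT3G10185, 0.862 for ARPN and 0.857 for TRY. In abcg14 on Split it was 0.894 for AT4G00590, 0.887 for AT1G24147, 0.883 for AT1G36510, 0.841 for AT3G04920 and 0.834 for AT2G27320. In Col-0 it was 0.849 for AT1G16860, 0.847 for SEC and 0.844 for AT1G10100 on Split, and 0.874 for RTFL7 and 0.837 for AT3G57580 on C.KNO3.

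The mutants differed from each other on C.KNO3, by a test of that difference, in ATMRK1 (2.30), bZIP58 (1.32), RTFL7 (1.08), SEC (1.00), AT3G04920 (0.99), AT5G42530 (-2.26), AT1G67860 (-1.18), AT1G33640 (-1.07), AT5G58390 (-0.91) and AT1G53800 (-0.54). Of these, ATMRK1, SEC, AT5G42530 and AT1G67860 passed in all 7 settings run for single genes, and the other 6 lost the call in 2 or more. Signal was also present in the 20904 probe sets with no gene named here. Of these, 231 were called in ipt3,5,7 and 579 in abcg14 on C.KNO3, and 134 and 381 on Split.

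A run of neighbouring genes on chromosome 3, SEC, AT3G04920 and GID1A among them, was higher in abcg14. Chance clustering of gene effects is argued against by shuffled gene orders, 0 of 1000 of which held a window as high. Variants of another accession that weaken probe binding would lower readings. The window of 15 genes with the largest median in either direction was at 0.85, and the highest in shuffled orders at 0.60. The run had been seen to be higher before this test was chosen, so the direction of the window was known. The test therefore adds no separate evidence on variants in the abcg14 line. An extra copy of the segment in the abcg14 line is a candidate explanation that stays open, since the 1 probe set for several genes that lay inside and took no part in finding the run was at 1.02, and 1 value is too few. An extra copy and a regulatory change shared by the neighbours cannot be told apart here, and no biological explanation was tested.

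The mutants differed from Col-0 along the axis on which the experiments also differ, the first principal component. Calls made by one part of the experiments stay open in part, since of the genes called in 2 experiments on C.KNO3 at least 91.4% had the same sign in the other 2, between the bounds set for and against that explanation. A state of the plants or of the RNA that varies between experiments and is stronger in the mutants may contribute. The mutant effect correlated across genes with experiments 3 and 4 minus 1 and 2 within Col-0 at r = 0.34, and at 0.19 and -0.06 when the experiments were paired in other ways. Plant state and RNA state cannot be told apart with these arrays, and an effect of cytokinin itself, which the design names, stays open.

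Genes that differ between the mutants were set beside the places of the mutated genes, with windows chosen when the locus codes of the called genes were in view. ATMRK1 lies 4 tested genes from IPT3. Of the 8 other called genes outside the chromosome 3 run that have a place on the map, 0 lay within 100 tested genes of IPT3, IPT5, IPT7 or ABCG14, as many as in 1000 of 1000 random draws, and 1, AT1G33640 at 105 genes from ABCG14, within 200, as many as in 515 of 1000. RTFL7 was also called and had no place in the table used. So few genes are expected in either window that DNA next to the mutated loci could neither be excluded nor found for these genes, and for ATMRK1 it was not tested.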

How the results depend on the processing

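Alternatives were chosen before the data were examined, except that the tests on experiments 1 and 2 alone, experiments 3 and 4 alone and without the chromosome 3 segment, the gene families and the minimum of 3 named members for a list test were chosen after. The block was among those set before, and it was put second after the counts of both fits had been seen. No named gene past the threshold changed direction. The majority of calls did turn on C.KNO3 in many settings, and in none for the mutants on Split. In ipt3,5,7 more calls were higher with the block (571 against 455 lower), after centring (114 and 103), without the dimmest genes (189 and 161), over all probe sets (221 and 193), in experiments 1 and 2 alone (81 and 71) and without ipt3,5,7 replicate 2 (224 and 218) or Col-0 replicate 3 (113 and 104). In abcg14 more were lower after quantile normalization (272 higher, 399 lower), in the fit on the groups alone (247 and 282), without the segment (288 and 306), in experiments 3 and 4 alone (121 and 156), without experiments 1 (123 and 181) or 4 (166 and 184), without replicates 1 (140 and 170) or 2 (142 and 143) of Col-0, and without replicates 1 (319 and 385) or 4 (122 and 131) of abcg14. Between the mutants the calls were 4 and 4 without the segment, and 1 higher and 2 lower in experiments 3 and 4 alone. Among lists that did not pass, scaling changed the sign of 2 medians near 0, the CC-type glutaredoxins in abcg14 on C.KNO3 (-0.01, 0.02 after quantile normalization) and the nitrate response in abcg14 on Split (-0.01, 0.02 after centring). Counts are given in the order ipt3,5,7 and abcg14 on C.KNO3, ipt3,5,7 and abcg14 on Split, and abcg14 against ipt3,5,7.

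With the experiment as a block the counts were 1026, 1459, 540, 786 and 62, and the overlap of the mutants on C.KNO3 was 716. A fit on the groups of the comparison alone gave 161 for ipt3,5,7 on C.KNO3, 234 for abcg14 on Split and 6 between the mutants. All 38408 probe sets gave 414, 1086 and 679 for ipt3,5,7 on C.KNO3 and abcg14 on both treatments, and 66 between the mutants, since more probe sets were tested. Experiments 1 and 2 alone gave 152, 394, 71, 208 and 18, and experiments 3 and 4 alone 128, 277, 45, 112 and 3. Without the segment 8 genes differed between the mutants. Controls divided between the mutants gave 12 to 33 shared genes. The fixed lists passed in 2 tests, in 0 with an estimated correlation, 1 with fry, 14 with the block, 1 without the dimmest genes, and 2 to 5 with an experiment left out.

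With 1 array left out the counts were 80 to 442, 253 to 723, 61 to 172, 147 to 367 and 24 to 28, and with a whole experiment left out 39 to 113, 207 to 350, 27 to 86, 107 to 184 and 12 to 18. Fewer arrays leave less power, which can lower a count. Lost power does not account for the rises to 442 without ipt3,5,7 replicate 2 and to 723 without Col-0 replicate 4. With 1 array left out, the experiments are also unequally held by the groups in a fit without the block. What moved the counts was not tested. Quantile normalization, centring, the filter on dim genes, the robust prior and the mean of probe sets kept each count within 1.5 times, and the Split counts stayed at 0 in every alternative. Of 659 values of named genes past the threshold under the alternatives, 154 no longer passed, 3 after quantile normalization, 0 with the block and 28, 45, 42 and 36 without experiments 1 to 4.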

Other observations

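The families by gene symbol were formed after few members of the fixed lists proved to have a named probe set, and their tests were chosen after that but before any family was tested. GH9 cellulases, enzymes that act on cell walls, were lower in both mutants, with medians over 19 genes of -0.32 in ipt3,5,7 and -0.26 in abcg14 on C.KNO3 (adjusted p = 0.00144 and 0.00245, and 0.611 and 0.504 with an estimated correlation). On Split their medians were -0.08 and -0.14 (adjusted p = 0.0248 and 0.0208, and 0.92 and 0.655 with an estimated correlation). The methionine sulfoxide reductases of the MSRB family had a median of -0.66 in ipt3,5,7 on C.KNO3 (adjusted p = 0.0231, and 0.606 with an estimated correlation), and did not pass in abcg14 there, at -0.35 (adjusted p = 0.0657, and 0.504 with an estimated correlation). Their median was -0.62 and -0.51 in ipt3,5,7 and abcg14 on Split (adjusted p = 0.00736 and 0.0108, and 0.317 and 0.521 with an estimated correlation).

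The 5 TUB tubulin genes were all below Col-0 in ipt3,5,7 on C.KNO3 (median -0.63, adjusted p = 0.0291, and 0.757 with an estimated correlation), and 0 of them was called singly in limma. In abcg14 on C.KNO3 the median was -0.58 and did not pass (adjusted p = 0.0657, and 0.663 with an estimated correlation), and on Split it was -0.53 and -0.44 (adjusted p = 0.0209 and 0.0254, and 0.92 and 0.655 with an estimated correlation). The 11 ATG autophagy genes, most of them members of the single ATG8 family, were all above Col-0 on C.KNO3 in both mutants, with medians of 0.25 and 0.26 (adjusted p = 0.0231 and 0.0245, and 0.757 and 0.663 with an estimated correlation). On Split the medians were 0.16 and 0.24, and that of ipt3,5,7 did not pass (adjusted p = 0.328 and 0.0383, and 0.953 and 0.655 with an estimated correlation). The 8 response regulators with a symbol or synonym in ARR, ARR15, RR16 and RR18 among them, were all below Col-0 in abcg14 on C.KNO3 (median -0.20, adjusted p = 0.0388, and 0.504 with an estimated correlation), of which ARR15 alone was called. Without ARR15 the other 7 did not pass (median -0.15, adjusted p = 0.129, and 0.663 with an estimated correlation), and the call of ARR15 itself was lost without 3 of the 4 experiments. The 8 genes did not pass in ipt3,5,7 on C.KNO3 (-0.10, adjusted p = 0.542) or on Split in either mutant (-0.01 and -0.11, adjusted p = 0.671 and 0.28), where the estimated correlation gave 0.816, 0.953 and 0.655. Quantile normalization and centring flipped none of the medians that passed. Of 64 families, 9 passed in ipt3,5,7 and 8 in abcg14 on C.KNO3, 4 and 9 on Split, and 0 for Split in Col-0, and with an estimated correlation 0 passed in each.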
